A study of Mus musculus with 6 samples.

How the data were processed

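Gene expression was measured by RNA sequencing in regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses, sorted from mouse ears. The labels describe mice that carry a Pparg-Tdt reporter and a Foxp3-thy1.1 reporter, that were 6 to 8 weeks old at the start and that then ate a normal chow diet (NCD) or a high-fat diet (HFD) for 16 weeks. Per the labels' protocols, cells were sorted by flow cytometry into lysis buffer and snap frozen, total RNA was purified with a small-scale column kit, cDNA was made with SMART-seq v4, a full-length method for low RNA input, and libraries were made with Nextera XT. That kit does not mark the strand, and the protocol names no molecular identifiers. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome build mm10. The version of the aligner, the read counter, the gene annotation and the rule behind the authors' detection filter are not given in the sources used here.

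The authors deposited 1 table of RPKM values (reads scaled to gene length and to a library total), with 1 column per library and 10298 rows, as the column names and the labels' descriptions say. Which reads make up that total is not given in the sources used here. The values carry 3 decimals, and the 6 columns sum to between 192624 and 201853 RPKM, which is not a read depth. The table as used here holds 0 columns of gene names or identifiers. Each row was taken as 1 gene, numbered by its place below the header, and a row number carries no information on which gene it is. Rows were not matched to genes by their order. The 40 gene lists fixed before the data were examined (23 for regulatory T cell, lipid and inflammatory programs, 15 for markers of other cell types, 2 for sex-linked controls) were therefore not tested, nor were single genes such as Foxp3 or Pparg, and gene length and GC content were not examined. No genome coordinates were used.

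Sequencing depth is unknown. Only 55 of the 61788 values lie under 0.1 RPKM, and steps of single reads were not visible. For each of the 15 pairs of libraries, the ratios of low values were tested against small whole-number ratios over a limited range of relative depths around equal depth. Larger differences in depth were not searched. In 5 pairs more rows fell on such a grid than after random jitter of the ratios, and in the other pairs as many or fewer did. HFD replicate 5 was in most of these 5 pairs, by small margins. They ran from 16 rows against 15 with HFD replicate 6 to 15 against 12 with NCD replicate 5. A lower depth of HFD replicate 5 is therefore not excluded. Counts were not recovered, so no count-based test, counting interval or detection limit is given.

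The labels' titles give the diet and the replicate number of each library: 3 HFD libraries (replicates 3, 5 and 6) and 3 NCD libraries (replicates 3, 5 and 6). The labels do not say whether the libraries of a diet came from separate mice, so p-values measure the spread between these libraries. No 2 columns are identical. Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with diet as the only term, moderated variances with an intensity trend, two-sided). The test covered the 9680 rows with a mean of at least 1 RPKM over the 6 libraries, and 618 rows fell below that filter. P-values were adjusted by the Benjamini-Hochberg method over the rows tested, with a threshold of 0.05. A log2 fold change on this scale is HFD minus NCD and understates the change of rows with low values. Intervals are 95% intervals from the moderated fit. Libraries were also compared by principal components and by correlations across rows, which are not independent replicates. The spread within each diet was compared by the median over rows of the SD of log2(RPKM + 1), with an exact permutation test over the 20 ways to place the libraries into groups of 3. With 3 libraries against 3, such a test cannot go below 0.1.

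The rule for the rows shown singly was set before the data were examined. It took rows past the adjusted threshold first. Where fewer than 5 passed in a direction, it was filled up to 8 rows with the smallest unadjusted p whose HFD libraries all lay on 1 side of all NCD libraries and whose mean was at least 5 RPKM in the higher group. Since the rows carry no names, only the first 2 in each direction are described singly. The parts of the rule that name genes could not be applied.

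The model was tested on simulated data of 9680 rows with the row means and moderated variances of this comparison. There were 20 simulations per fold size with 200 rows changed. Rows were drawn independently with normal noise of the same variance in all 6 libraries, and folds were applied to RPKM itself. The wider spread between HFD libraries was not simulated. The model recovered 26.4% of rows changed 1.5-fold, 77.1% of rows changed 2-fold, 96% of rows changed 3-fold and 98.3% of rows changed 4-fold. With no rows changed, it called a mean of 0.75 rows. Among the unchanged rows, it called a mean of 4.8 when the others were changed 1.5-fold and 10.8 when they were changed 2-fold. Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, median-of-ratios scaling, equal column sums, quantile normalization, variances without a trend, robust variances, library weights, the replicate number as a block, an adjusted threshold of 0.1, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.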

Results

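The data comprised 6 RNA-seq libraries of regulatory T cells sorted from the ears of mice kept for 16 weeks on a normal chow diet (NCD, n = 3) or a high-fat diet (HFD, n = 3). The comparison asked how a high-fat diet alters the gene expression profile of regulatory T cells in the skin. The mice carried reporters for Foxp3, the transcription factor that defines regulatory T cells, and for Pparg, which encodes a lipid-sensing nuclear receptor. The table held 10298 rows of RPKM values and no gene names, so the results describe how many genes differed, by how much and at what level, and name none of them.

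Median expression levels were close in the 6 libraries, but HFD replicate 5 had the widest distribution. The median RPKM ranged from 7.11 in HFD replicate 5 to 7.40 in NCD replicate 6. The lower quartile was 2.81 RPKM in HFD replicate 5 and 3 to 3.11 RPKM in the other libraries, and the upper quartile was 17.6 RPKM in HFD replicate 5 and 16.8 to 17.3 RPKM in the others. Between 4111 and 4196 rows reached 10 RPKM in a library. The 10 most abundant rows took between 5.58% and 5.71% of a library's summed RPKM. The most abundant row had 1940 ± 143 RPKM (SD, n = 3) in HFD and 1830 ± 33.7 RPKM (SD, n = 3) in NCD, a difference within the spread between replicates (limma, adjusted p = 0.814). Read depth was unknown, so the precision of each value rests on the replicates alone.

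The libraries did not fall into 2 clean groups by diet. The first principal component, with 33.4% of the variance, set HFD replicate 5 apart at a score of 26.3, while the other 5 libraries lay between -8.1 and 3.2. On the second component, with 19.8% of the variance, HFD replicates 3 and 6 scored -13.2 and -12.1, and the 3 NCD libraries scored from 3.6 to 13.4, but HFD replicate 5 scored 4.3, among the NCD libraries. On the third, with 19.5% of the variance, HFD replicates 3 and 6 lay at opposite ends, at -14.8 and 15.9, with the NCD libraries from -6.6 to 1.2 and HFD replicate 5 at 4.3. Pearson correlations across the tested rows were 0.981 to 0.983 between NCD libraries, 0.968 to 0.976 between HFD libraries and 0.969 to 0.981 between diets. Spearman correlations were 0.976 to 0.979, 0.958 to 0.969 and 0.960 to 0.976, respectively.

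**Figure D1:**
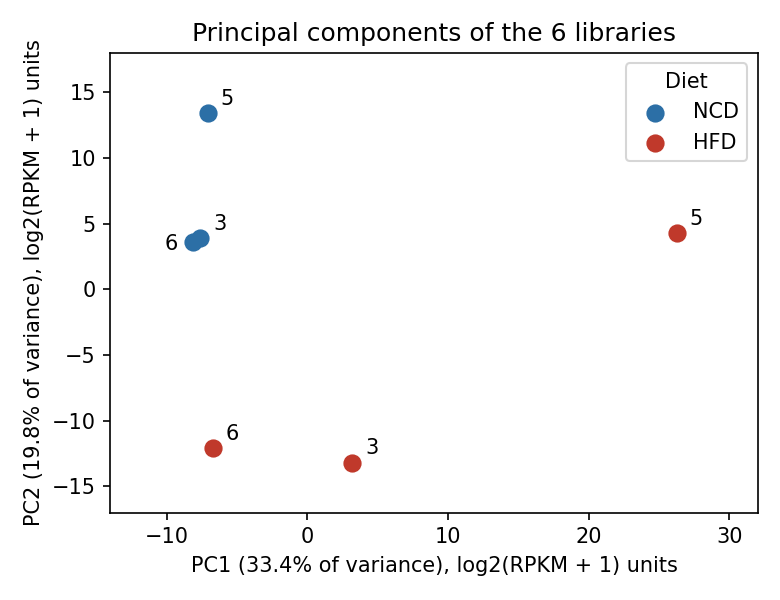
Scores of the 6 libraries on the first and second principal components of log2(RPKM + 1), coloured by diet and numbered by replicate. HFD replicate 5 stands alone at 26.3 on the first component, and HFD replicates 3 and 6 lie below the NCD libraries on the second.

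Most genes had the larger spread between the HFD libraries, at the limit of what 3 libraries against 3 can test. The median SD of log2(RPKM + 1) was 0.19 in HFD and 0.14 in NCD, and 64.1% of the 9680 tested rows had the larger SD in HFD. In an exact permutation test of the difference in median SD (two-sided, 3 against 3), p was 0.1, the smallest value this design allows. Without HFD replicate 5, the share with the larger SD in HFD was 49.9%, against 42.3% for equal normal spread when an SD over 2 libraries is set against an SD over 3. Compared pair against pair, HFD replicates 3 and 6 differed more than an NCD pair in 55.2% to 57.9% of rows, depending on the NCD pair.

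No gene passed the test for a difference between diets. Of the 9680 rows, 0 were higher and 0 were lower in HFD at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 0 passed at 0.1. The smallest adjusted p was 0.176, shared by 3 rows. At an unadjusted p under 0.05 there were 764 rows (7.89%), of which 377 were higher and 387 lower in HFD, where uniform p-values would give 484. That balance depended on the scaling, with 336 higher and 445 lower under equal column sums and 437 higher and 357 lower under median-of-ratios scaling. In 1335 rows (13.8%), the HFD libraries all lay on 1 side of all NCD libraries, with 634 rows higher and 701 lower in HFD. Apart from ties, the mean over all 10 splits of the 6 libraries into 3 and 3 is 10%, or 968 rows. This count was not made for the other splits, and rows are not independent, so no excess over chance can be read from it. Without NCD replicate 5 the number at an unadjusted p under 0.05 was 480, close to the 484 that uniform p-values give, and without HFD replicate 6 it was 1161, with 3 rows past the adjusted threshold.

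**Figure D2:**
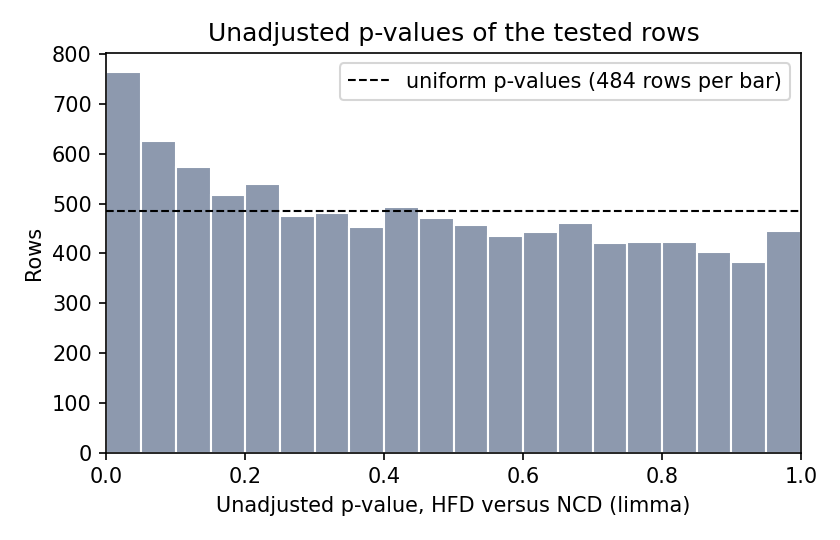
Histogram of the unadjusted limma p-values of the 9680 tested rows in bars of width 0.05, with a dashed line at the 484 rows per bar that uniform p-values give. The first bar holds 764 rows, and the counts fall towards the right.

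On the log2(RPKM + 1) scale, the differences between diets were small relative to 2-fold in most genes. The median absolute log2 fold change was 0.13 and the 95th percentile was 0.43, against a median standard error of 0.16. The 95% interval of the fold change lay within 2-fold in both directions for 9416 rows (97.3%), and within 1.5-fold for 6793 rows (70.2%). Among the 6357 rows with a mean of at least 5 RPKM, where the pseudocount compresses fold changes less, it lay within 2-fold for 6240 (98.2%). Only 14 estimates exceeded 2-fold on this scale, 7 higher and 7 lower in HFD, and 13 of these had an unadjusted p under 0.05. Rows under 2-fold on this scale can exceed it in RPKM. Row 1461 had a ratio of mean RPKM of 2.16 at a log2 fold change of 0.95, and row 3723 had 0.48 at -0.94. The interval lay wholly beyond 1.5-fold in 3 rows and wholly beyond 2-fold in 0 rows. Recovery was estimated in simulated data with independent rows, moderated variances that were the same in every library, and folds applied to RPKM itself. With 200 of the 9680 rows changed, limma recovered 77.1% of rows changed 2-fold and 26.4% of rows changed 1.5-fold. Moderated variances differ less between rows than the measured variances do, which can raise recovery in simulated data. The wider spread between HFD libraries was not simulated either, so recovery in these libraries may differ and may be lower.

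The rows described singly were chosen for small unadjusted p-values and for HFD libraries that all lay on 1 side of the NCD libraries, so that separation is part of the choice, and none passed the adjusted threshold. Row 1076 had 6.21 ± 1.26 RPKM in HFD and 2.22 ± 0.411 RPKM in NCD (SD, n = 3 each), with a log2 fold change of 1.15 ± 0.18 (SE) and an adjusted p of 0.176 (limma). That fold change was 0.63 with a pseudocount of 5 and 1.44 with a pseudocount of 0.1. Row 2383, an abundant transcript, had 92.6 ± 9.58 RPKM in HFD and 54.7 ± 8.89 RPKM in NCD, with a log2 fold change of 0.76 ± 0.13 (SE) and an adjusted p of 0.228. In the other direction, row 2167 had 56.9 ± 8.21 RPKM in HFD and 99.3 ± 10.5 RPKM in NCD, with a log2 fold change of -0.80 ± 0.12 (SE) and an adjusted p of 0.176. Row 3723 had 5.28 ± 0.65 RPKM in HFD and 11.0 ± 1.15 RPKM in NCD, with a log2 fold change of -0.94 ± 0.15 (SE) and an adjusted p of 0.176. The 8 leading rows on the higher side had log2 fold changes of 0.54 to 1.15, and the 8 on the lower side had -1.07 to -0.52, with adjusted p-values of 0.176 to 0.302 over both sides. Row 2167 passed without HFD replicate 6 (limma, adjusted p = 0.0292). It also passed with the replicate number as a block (limma, adjusted p = 0.0405), although no label says that the numbers mark pairs.

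**Figure D3:**
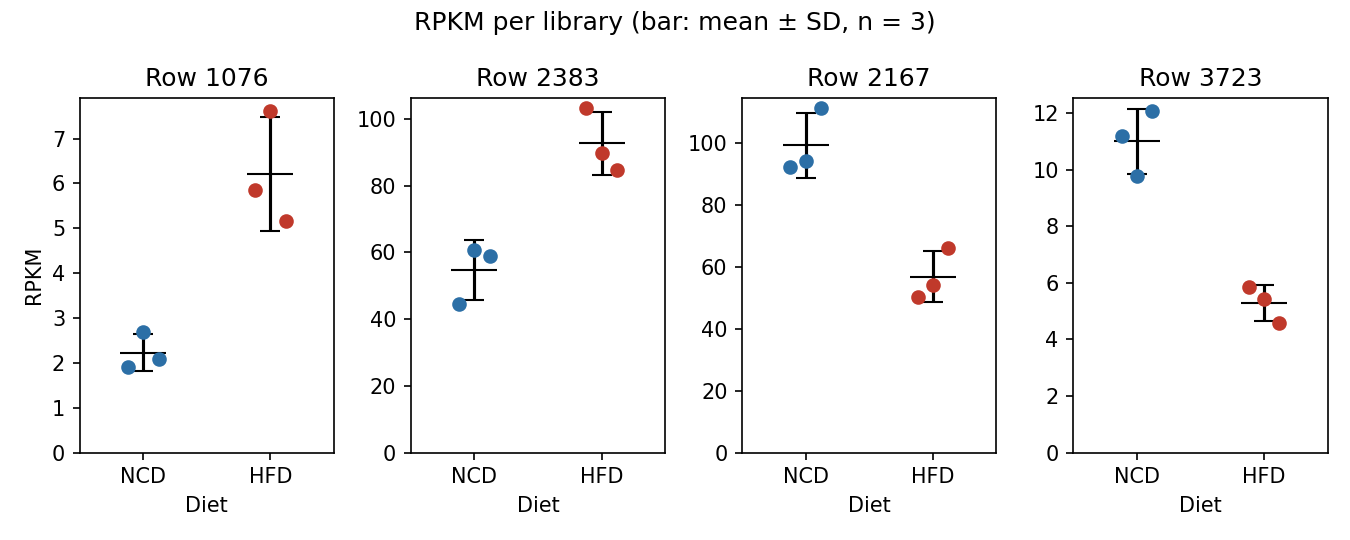
RPKM in each library for the 2 leading rows on the higher side (1076 and 2383) and the 2 on the lower side (2167 and 3723), with points for the 3 libraries of each diet and bars for mean ± SD. The rows were chosen so that the HFD and NCD points do not overlap, and none of the 4 passed the adjusted threshold.

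The direction of the unadjusted differences varied with expression level. Of the rows at an unadjusted p under 0.05 in the most abundant decile (968 rows, mean of 40.1 RPKM or more), 79 were higher and 34 lower in HFD, so that 69.9% were higher (95% exact binomial interval 60.6% to 78.2%, which treats rows as independent). In the least abundant decile (968 rows, mean of 2.14 RPKM or less) 31 were higher and 48 lower. The median log2 fold change was -0.03 in the least abundant decile, -0.05 in deciles 3 and 4 and 0.03 in the most abundant. Under quantile normalization, which gives every library the same distribution and so largely sets this balance, the most abundant decile held 63 rows higher and 62 lower. Without HFD replicate 5 it held 52 higher and 41 lower.

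**Figure D4:**
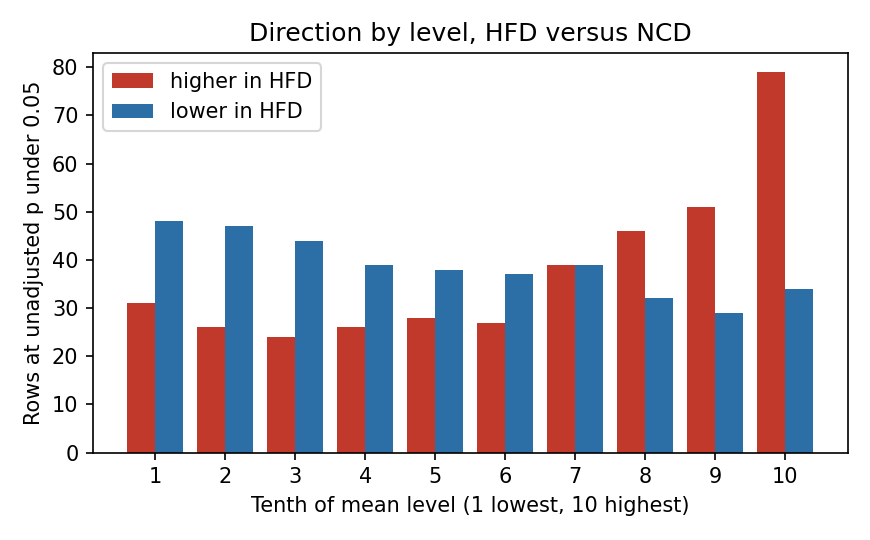
Number of rows at an unadjusted p under 0.05 that were higher or lower in HFD, in deciles of mean log2(RPKM + 1) from the lowest (1) to the highest (10), with 968 rows in each. Rows lower in HFD are the more numerous in deciles 1 to 6, and rows higher in HFD in deciles 8 to 10, where the most abundant decile holds 79 higher and 34 lower.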

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

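The 0 rows past the adjusted threshold stayed at 0 under 16 of 18 alternatives. The exceptions were the replicate block, which called 1 row (row 2167, adjusted p = 0.0405), and the fit without HFD replicate 6, which called 3. Leaving out each library in turn gave 0 to 3 calls. The 3 were row 2167 (log2 fold change -0.91, adjusted p = 0.0292) and rows 756 and 3192, both named after their values were seen. Row 756 had 22.1 and 27.8 RPKM in HFD replicates 3 and 5 but 6.02 RPKM in HFD replicate 6, against 7.78 to 8.82 RPKM in NCD. Row 3192 had 30.1 and 30.8 RPKM in those replicates but 9.62 RPKM in HFD replicate 6, against 8.45 to 10.8 RPKM in NCD. With all libraries their adjusted p-values were 0.643 and 0.486. The alternatives for the other counts and shares were chosen after seeing the data. The 764 rows at an unadjusted p under 0.05 became 480 to 1161 when each library was left out in turn (480 without NCD replicate 5, 1161 without HFD replicate 6) and stayed within 1.5 times under the other alternatives. The share of higher rows in the most abundant decile, 69.9% with all libraries, was 50.4% under quantile normalization and 55.9% to 75.4% when each library was left out in turn. The share of rows with the larger SD in HFD, 64.1%, was 66.4% with a filter at 5 RPKM and 62.0% under quantile normalization. When each library was left out in turn it was 49.9% to 70.4%, with 49.9% without HFD replicate 5. Equal normal spread would give 42.3% without an HFD library and 57.7% without an NCD library. Of the 67 fits of the alternatives for the 4 rows described singly, 2, both of row 2167, were past the threshold. Their direction could hardly turn, since they were chosen for separated diets, but the log2 fold change of row 1076 ran from 0.63 to 1.44. Same-numbered libraries deviated from their diet's mean with a correlation of 0.08 for each of the 3 numbers, which does not establish pairs. All 6 libraries correlated best with their own number, a hint from the data and not from the design. Deviations from a diet's mean sum to 0, so these 6 matches are not independent and the hint is weak. The alternatives planned for gene lists, listed genes and markers of other cell types were not run, because the rows carry no names. Depth is unknown, so its limits are not given.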

Other observations

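The tests in this part were chosen after the results they bear on were seen, though 2 of them, the share of higher rows without HFD replicate 5 and the spread after quantile normalization, had their predictions written before their values were computed. Each is reported as a test of a hypothesis on the same data.

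Whether diet is what gave 764 rows at an unadjusted p under 0.05 cannot be settled with these libraries. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Of these, 1 split, the real one, gave as many as 764 rows, and the highest of the others gave 684. That split grouped HFD replicates 3 and 5 with NCD replicate 3. The splits that held HFD replicates 3 and 5 together gave 764, 684, 601 and 487 rows, and the others gave 233 to 412. For rows past the adjusted threshold, the real split gave 0 and the highest of the others gave 1, and since no split can give fewer than 0, that all 10 gave at least as many carries no information. A modest diet effect spread over many genes could give the rise of low p-values over the uniform level. The counts were highest in the splits that held HFD replicates 3 and 5 together, whichever library joined them. Such splits retain part of any diet effect, so this pattern does not tell a diet effect from a likeness of those libraries. Of the 6 fits that left out 1 library, 5 gave 557 to 1161 rows. The fit without NCD replicate 5 gave 480. That fit had fewer libraries, and the splits other than the real one gave 233 to 684 rows. The 480 therefore does not show that the rise vanished, and the part of diet stays open.

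HFD replicate 5 differed most from the other libraries at every level of expression. The SD over rows of its difference from the mean of the other 5 libraries was 0.33 on the log2 scale, against 0.224 to 0.26 for the others, and it was the highest in each of the 10 deciles of level, from 0.327 against 0.321 or less in the least abundant to 0.256 against 0.168 or less in the most abundant. Fewer reads or fewer starting molecules would add variance that falls in proportion to level, but while the median level rose 48.8-fold from the least to the most abundant decile, the excess variance fell only to 0.612 of its value (bootstrap over rows 0.366 to 1.67, pseudocount 0.1), which argues against this as the whole cause. A level-dependent scaling difference is argued against as the whole cause too. After quantile normalization, the SD of HFD replicate 5 was still 1.23 times the highest of the others. Another cell mixture, RNA quality and a real difference in that sample stay open, as they were not tested without gene names, and no biological explanation was tested because the design sets no library apart within a diet.

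The lean of abundant genes towards HFD may come partly from this one library. Its median deviation from the other libraries ran from -0.07 in the least abundant decile to 0.09 in the most abundant. Without it, 55.9% of the rows at an unadjusted p under 0.05 in the most abundant decile were higher in HFD, against 69.9% with it. The 55.9% lies within the 39.8% to 60.2% that an even split allows if rows are independent. However, over all rows at an unadjusted p under 0.05, 44.3% were higher without this library and 49.3% with it. Relative to all rows, the most abundant decile thus still leaned towards HFD without it, though less. In the most abundant decile the median deviation was 0.02 for HFD replicate 3 but -0.04 for HFD replicate 6, against the lean, and -0.06 for NCD replicate 6. An effect of diet on abundant genes is not excluded, since 52 of those rows were still higher and 41 lower.

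HFD replicate 5 alone may not be the reason for the larger spread between HFD libraries, but these libraries cannot settle it. HFD replicates 3 and 6 differed from each other more than an NCD pair in at least 55.2% of rows, for each of the 3 NCD pairs. This sets a single HFD pair against NCD pairs that share libraries. Rows are not independent, so that share has no spread to be judged against. Limma's library weights were 0.55 for HFD replicate 5 and 0.69 for HFD replicate 6, and 1.09 to 1.62 for the NCD libraries. HFD replicate 3 had 1.15, within the NCD range. The weights came from a fit that included HFD replicate 5, so they are not separate evidence on the other HFD libraries. The diet stays open, since the exact permutation test of the spread gave 0.1, the smallest p it can give. A lower depth of HFD replicates 3 and 6 was not tested.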
